A study of Mus musculus with 4 samples.

How the data were processed

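Total RNA was sequenced from 4 libraries of stimulated mouse B cells, 2 from B10+ cells and 2 from B10− cells. Per the labels' protocols, C57BL/6 splenic B cells were kept with an anti-Cd40 antibody for 48 h and received LPS, PMA and ionomycin for the last 5 h. RNA was taken up in Trizol and ribosomal RNA was depleted with Ribo-Zero. Per the labels, replicate 1 of both subsets came from the same cell culture, and replicate 2 of both subsets from another culture. These are called culture 1 and culture 2 here.

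The authors deposited 1 table of FPKM values (fragments scaled for transcript length and for the size of the library), per the labels, with 1 column for each library and 1 gene symbol and locus for each of 23699 entries. The submitters' processing notes name TopHat 1.3.2, Cufflinks 2.1.1, bcl2fastq 1.8.4, DESeq without a version, and the genome build mm9, with no role or order given for them. Settings of these tools, the annotation used and the handling of strand and of reads with several matches are not given in the sources used here. The low values did not step in whole reads, so no counts were recovered and depth is unknown. No counting interval or detection floor is given for that reason, and a gene listed at 0 is described only as listed at 0. FPKM values are relative within a library, so a few very abundant RNAs can lower the values of all other genes.

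Of the 23699 entries, 3764 were listed at 0 in every library. The symbols of 25 entries had become 5-digit numbers, as happens when a spreadsheet reads a symbol as a date, and these were kept but not named. Starts of loci in the table count from 0, since end minus start equalled the RefSeq gene length for 8690 of 20477 matched symbols, against 528 when 1 was added. Coordinates are therefore printed with 1 added to the start, on mm9. The reference annotation in use (GRCm38) is another build and served only for transcript length and GC content by gene symbol. Mitochondrially encoded genes were not analysed here.

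Values were tested as log2(FPKM + 1), and log2 differences on this scale understate the change of genes with low values. An entry was tested when it reached 1 FPKM in at least 2 libraries, which left 10367 entries with 10324 symbols. Of these, 75 tested entries share a symbol with another locus. The test was limma-trend (limma 3.58.1 in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all tested entries and a threshold of 0.05. The fit chosen before the data were examined had no term for the culture, and the fit with the culture as a replicate block was set down beside it. The labels pair the libraries by culture, so both are reported. The pairing check gave a Pearson correlation of log2 values of 0.965 and 0.947 between the libraries of a culture, against 0.840 for the B10+ pair and 0.836 for the B10− pair. Deviations from the group means correlated at 0.865 across genes within a culture. The first principal component held 81.1% of the variance and separated the cultures, and the second held 13.9% and separated the subsets. Each culture holds 1 library of each subset, so culture and subset are not confounded. Replicates are separate cultures per the labels, and there are only 2. The fit with the block leaves 1 residual degree of freedom. Its p-values therefore rest largely on the spread that limma-trend estimates over all genes, not on a gene's own spread between the cultures. Pdcd1, for example, has an SD over cultures of 0.048 but a standard error of 0.164 in that fit.

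Gene groups were 28 lists fixed before the data were examined: programmes of stimulated B cells, markers of other spleen cell types, and quality lists. The 24 lists with at least 3 tested members were tested with camera from limma at a preset correlation of 0.01, adjusted over the lists. An estimated correlation and fry, which asks whether the genes of a set move on balance in a single direction, were alternatives. With an estimated correlation, camera tests on the few residual degrees of freedom of the fit, so a missed call there says little. Counts of members are given over all tested entries and adjusted over the list alone. Where a symbol had several loci, the locus with the highest mean entered a list.

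Genes were named by a rule fixed before the data were examined. It takes the sort genes, of which Il10, Cd1d1 and Cd5 are given, and some results are not reported here. It takes up to 10 higher and 10 lower genes with the largest log2 difference among those past the threshold, with the same direction in both cultures and a mean of at least 5 FPKM in the higher group. Predicted, receptor-segment and olfactory symbols are left out of that part. It takes for each list the 4 members with the smallest p without the block, and every member behind a count of 5 or fewer. Because the fit without the block called no gene, the part on the largest differences was applied to the calls with the culture block, a choice made after seeing the data. Genes chosen after their values were seen are said to be so.

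The scripts were tested on simulated data with the real culture means and estimated spread. For B10+ against B10− cells over 10367 entries, the fit without the block recovered 0% of changed genes at log2 differences of 1, 2 and 3. With the culture block it recovered 16.4%, 89.6% and 98.5% in turn, and 0.108% of unchanged genes were called. The simulated spread was drawn from the model of the blocked fit, and changed genes had a mean log2 value above 2. These rates therefore hold only under that model, and do not test the calls made on the real data. The alternatives tried were quantile normalization, no filter on low values, a minimum of 5 FPKM, a pseudocount of 0.1, robust eBayes and leaving out each library in turn. Each of these except the last was also combined with the culture block, and entries spanning under 200 bp were left out, both chosen after seeing the data. A fit without a library sets unequal numbers of libraries per culture against each other. The culture difference enters it, so calls kept or lost there do not measure the subset difference alone. Figures were drawn with matplotlib 3.10.9.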

Results

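RNA was measured in 2 subsets of mouse splenic B cells sorted from the same stimulated cultures. B10+ cells were sorted as Cd1d high, Cd5 positive and positive for Il10, the anti-inflammatory cytokine interleukin 10. B10− cells were negative for Cd1d, Cd5 and Il10. Each subset has 2 libraries, and each of 2 cultures gave 1 library of each subset. The values are the authors' FPKM, and the depth of the libraries is unknown. At least 1 FPKM was reached by 10132 and 9934 gene entries in B10+ replicates 1 and 2, and by 10017 and 9568 in B10− replicates 1 and 2. Entries listed at 0 made up 19.4% of B10+ replicate 1, against 34.6%, 36.2% and 37.3% in B10− replicate 1, B10+ replicate 2 and B10− replicate 2. The comparison asks which genes differ between Il10-producing B cells and the B cells of the same culture sorted as negative for Cd1d, Cd5 and Il10.

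The genes used for the sort were read first, and their differences follow from the sort. Il10 (chromosome 1, 132916422 to 132921547, mm9) reached 1683 and 2329 FPKM in the B10+ libraries of cultures 1 and 2, against 9.26 and 9.62 FPKM in B10− cells. The log2 difference was 7.57 ± 0.30 (SD over 2 cultures), with a limma adjusted p of 0.144 without the culture and 0.00276 with the culture as a replicate block. Cd5 (chromosome 19, 10792633 to 10813464) was at 2.51 ± 0.18 FPKM in B10+ and 0.421 ± 0.202 FPKM in B10− cells (SD, n = 2), and Cd1d1 (chromosome 3, 86799758 to 86803262) at 1.82 ± 1.33 and 0.625 ± 0.551 FPKM (SD, n = 2). Both were higher in B10+ cells in each culture. Their limma adjusted p with the block was 0.0581 and 0.174, past the threshold for neither. As a list the sort genes were higher in B10+ cells (camera adjusted p = 5.79e-07, and adjusted p = 0.198 with an estimated correlation). Il10 and Cd5 passed without the block, and Cd1d1 also with it, when adjusted over the list alone.

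With the culture as a replicate block, 81 entries were higher and 8 lower in B10+ cells. Of the 81 higher entries, 35 were entries of replication-type histone genes, some of which overlap, and 46 were others. Besides Il10, the largest rises were of Il19 (an Il10-family cytokine), Csf2rb (the shared beta chain of the Il3, Il5 and Gm-csf receptors), Pdcd1 (the inhibitory receptor PD-1), Tpbg, Xcl1 (a chemokine that attracts dendritic cells), Timd2 and the histone genes Hist2h2aa2, Hist1h2bn and Hist1h2bk. Il19 (chromosome 1, 132829233 to 132835818) rose from 0.290 ± 0.086 to 14.2 ± 3.61 FPKM (SD, n = 2), a log2 difference of 3.54 ± 0.44 (SD over 2 cultures; limma adjusted p with the block = 0.026). Pdcd1 was at 34.5 and 21.6 FPKM in the B10+ libraries against 3.24 and 1.82 FPKM, and Csf2rb at 21.6 and 9.06 against 1.68 and 0.240 FPKM, in cultures 1 and 2. Their log2 differences were 3.03 ± 0.05 and 3.05 ± 0.04 (SD over 2 cultures), each with a limma adjusted p of 0.026 with the block. Tpbg had a log2 difference of 3.03 ± 0.45 and a limma adjusted p of 0.0287 in the same fit.

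The 8 lower entries with the block were Satb1 (a chromatin organizer of lymphocytes), Samsn1, Ifitm2 (an interferon-induced membrane protein), Arap2, Epb4.1l4b, Hnrnpa1, Mir3096 and Mir219-1. Satb1 was at 10.9 and 92.6 FPKM in B10+ against 44.0 and 287 FPKM in B10− cells, a log2 difference of -1.77 ± 0.21 (SD over 2 cultures; limma adjusted p with the block = 0.0371). Samsn1, an adaptor protein, differed by -1.64 ± 0.23 and Ifitm2 by -1.58 ± 0.05 on the log2 scale (SD over 2 cultures; limma adjusted p with the block = 0.0396 and 0.0384). Arap2 and Epb4.1l4b differed by -1.56 ± 0.25 and -1.98 ± 0.35 (limma adjusted p with the block = 0.0459 and 0.0434). Hnrnpa1 was at 6.55 and 21.0 FPKM in B10+ against 56.1 and 226 FPKM in B10− cells (limma adjusted p with the block = 0.026), and its locus overlaps the predicted genes Gm5643 and Gm10052. Gm5643 was at 235 FPKM in B10+ against 12.6 FPKM in B10− cells of culture 2, the opposite direction, and at 98.0 against 136 FPKM in culture 1. Summed over the 3 loci, the signal was 259 against 244 FPKM in culture 2 and 104.5 against 192.3 FPKM in culture 1, so the fall of Hnrnpa1 is uncertain. Mir3096 and Mir219-1 were listed at 0 in both B10+ libraries and span under 200 bp.

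Without the culture in the model, limma called 0 entries in either direction at the adjusted threshold, with 109 higher and 9 lower entries at an unadjusted p under 0.05 and a smallest adjusted p of 0.0959. The libraries of different cultures differed by more than the subsets did, and this spread enters the error of that fit. The difference between subsets had the same sign in both cultures for 6760 of 10367 entries (65.2%), and 236 entries were more than 2-fold higher and 25 more than 2-fold lower in both. Across genes, which are not independent replicates, the differences in the 2 cultures correlated with a Pearson r of 0.514 and a Spearman rho of 0.446.

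**Figure D1:**
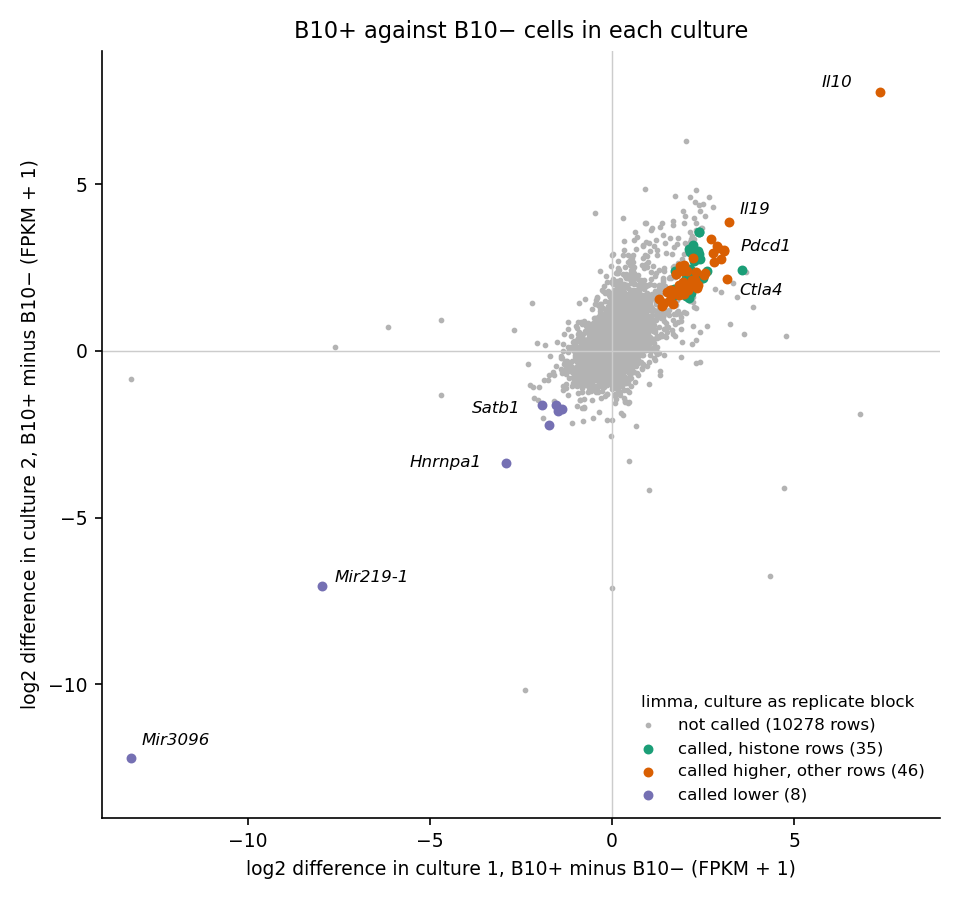
Log2 difference between B10+ and B10− cells, log2(FPKM + 1), in culture 1 (horizontal axis) and culture 2 (vertical axis) for 10367 tested entries, coloured where limma with the culture as a replicate block called them. Il10 lies at 7.36 and 7.78.

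Genes that regulatory B cells are known to use rose as a group. This list held 21 tested genes, 15 higher and 5 lower in both cultures, with a median log2 difference of 0.97 (camera adjusted p = 2.41e-13, and adjusted p = 0.198 with an estimated correlation). Over all genes, 4 members rose with the replicate block and 0 without it. They were Ctla4 (an inhibitory receptor that competes for Cd80 and Cd86), Timd2 and Havcr1 (Tim-family receptors, Havcr1 being Tim-1) and Lgals1 (galectin-1). Ctla4 was at 244 and 138 FPKM in B10+ against 26.7 and 29.9 FPKM in B10− cells, a log2 difference of 2.66 ± 0.69 (SD over 2 cultures; limma adjusted p with the block = 0.0464). Havcr1 was at 31.8 and 105 against 8.03 and 17.4 FPKM, and Timd2 at 74.6 and 36.4 against 9.08 and 3.44 FPKM (limma adjusted p with the block = 0.0449 and 0.026). With the adjustment over the list alone, 12 members were higher and 3 lower with the block, and 4 passed without it (Ctla4, Lgals3, Timd2 and Tigit). Tigit, another inhibitory receptor, was at 9.16 and 19.4 against 2.12 and 1.34 FPKM, and Ebi3, a subunit of interleukins 27 and 35, at 107 and 84.7 against 52.3 and 44.4 FPKM. Beside this list, the 3 tested T cell markers were higher in B10+ cells too (camera adjusted p = 0.0258, and adjusted p = 0.712 with an estimated correlation). With no filter on low values, which brings in all 17 T cell markers, the camera adjusted p was 5.03e-07, and 1.04e-05 with the replicate block. The 3 lower members of the regulatory list were Cd274 (PD-L1), Pdcd1lg2 (PD-L2) and Socs3, with log2 differences of -0.79, -0.79 and -0.63. Fasl stayed below 1 FPKM in all 4 libraries.

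Cytokine and chemokine genes were also higher in B10+ cells. Of 25 tested members, 16 were higher and 4 lower in both cultures, with a median log2 difference of 1.28 (camera adjusted p = 8.24e-13, and adjusted p = 0.198 with an estimated correlation). Over all genes, 4 rose with the replicate block and 0 without it: Xcl1, Il27, Il21 and Ifng. Xcl1 was at 13.0 and 26.6 FPKM against 0.883 and 2.14 FPKM, and Il27 (the p28 subunit of interleukin 27) at 40.0 and 10.6 against 4.17 and 0.724 FPKM (limma adjusted p with the block = 0.026 for each). Il21 and Ifng were lower in level, at 3.01 and 4.02 against 0.261 and 0.525 FPKM and at 3.51 and 5.36 against 0.253 and 0.972 FPKM (limma adjusted p with the block = 0.0395 and 0.0396). With the block 14 members were higher and 2 lower adjusted over the list alone, and 0 passed without it. Tnfsf8 and Tnfsf9, ligands of Cd30 and 4-1BB, had log2 differences of 2.51 ± 0.65 and 2.44 ± 0.66 (SD over 2 cultures) and a limma adjusted p of 0.0514 and 0.0566 with the block. The 3 tested T cell markers were also higher in B10+ cells as a list (camera adjusted p = 0.0258, and adjusted p = 0.712 with an estimated correlation). With all 17 T cell markers and no filter on low values, the camera adjusted p was 5.03e-07, and 1.04e-05 with the replicate block. The 2 lower members of the cytokine list were Ccl3 and Il1b, with log2 differences of -1.16 and -0.60.

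Genes of B-1 and marginal zone B cells, the innate-like B cell subsets, were higher in B10+ cells (19 tested, 14 higher and 2 lower in both cultures, median log2 difference 0.96, camera adjusted p = 7.07e-11, and adjusted p = 0.198 with an estimated correlation). B10+ cells were sorted as Cd1d high and Cd5 positive and B10− cells as negative for both, so this list is not independent of the sort. Nid1 and Rgs10 rose over all genes with the replicate block, Nid1 from 0.278 ± 0.209 to 4.72 ± 0.395 FPKM and Rgs10 from 2.43 ± 2.48 to 18.3 ± 15.4 FPKM (SD, n = 2; limma adjusted p with the block = 0.0386 and 0.0287). In this list 11 members were higher and 1 lower with the block adjusted over the list alone, and 0 passed without it. Zbtb32 was at 501 and 378 against 153 and 63.8 FPKM, and Ahnak at 8.31 and 10.8 against 3.13 and 2.38 FPKM. Cd9, a tetraspanin, had a log2 difference of 3.08, with 18.4 and 65.1 FPKM in the B10+ libraries. The member lower with the block over the list alone was Tbx21 (T-bet), at 3.97 and 8.67 against 9.95 and 12.3 FPKM. Leaving out a library lets the culture difference into the fit, so such fits are not taken as support for the regulatory, cytokine and B-1 lists. T cell markers (camera adjusted p = 0.0258, and 5.03e-07 with no filter on low values) and macrophage and monocyte markers (0.00206) were higher as lists too. Each of these 2 lists had an adjusted p of 0.712 with an estimated correlation.

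**Figure D2:**
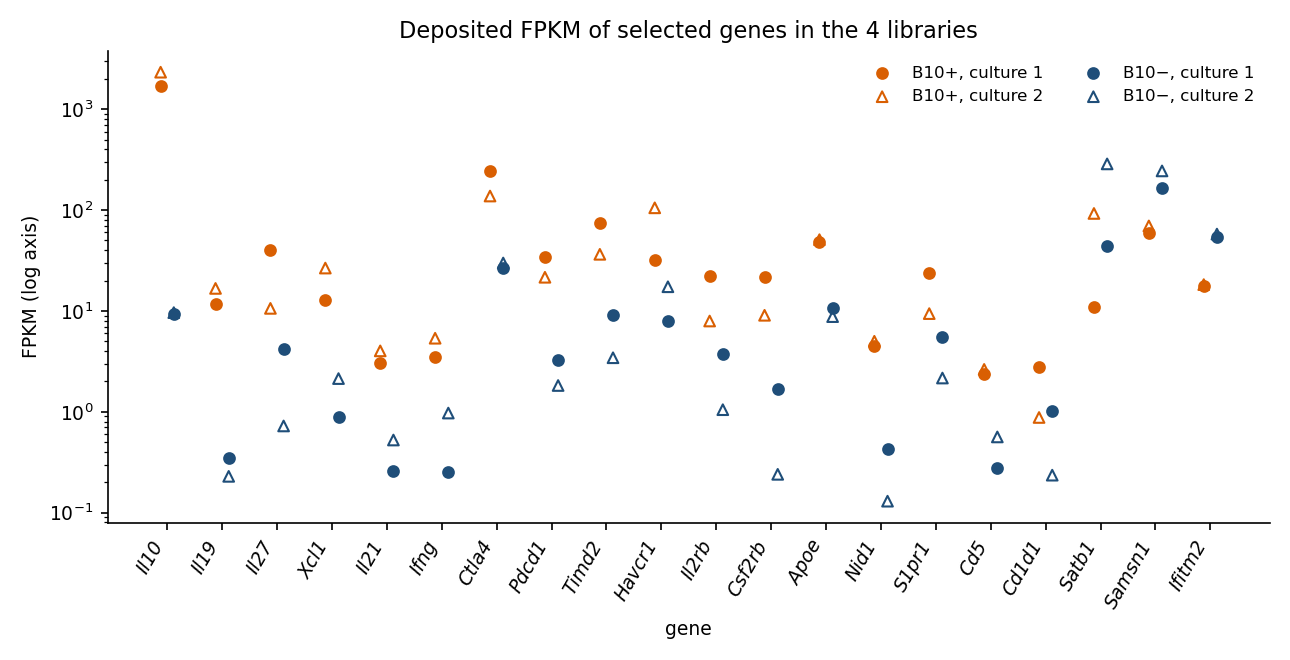
Deposited FPKM (vertical log axis) of 20 genes in the 4 libraries, with colour for the subset and marker shape for the culture. Il10 was at 1683 and 2329 FPKM in the B10+ libraries and at 9.26 and 9.62 FPKM in the B10− libraries.

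Cell cycle genes were higher in B10+ cells, with a median log2 difference of 1.47 over 40 tested members, 34 of them higher and 0 lower in both cultures (camera adjusted p = 1.03e-14, and adjusted p = 0.712 with an estimated correlation). The median was 0.65 in culture 1 and 2.35 in culture 2. The genes with the smallest p were Ube2c, Cenpf, Plk1 and Cenpe, all of mitosis. Ube2c was at 52.5 and 27.8 FPKM in B10+ against 9.24 and 0.403 FPKM in B10− cells, and Plk1 at 10.9 and 6.37 against 4.48 and 0.263 FPKM. Cenpf and Cenpe had log2 differences of 1.82 ± 1.18 and 1.71 ± 1.24 (SD over 2 cultures). No member passed limma over all genes, with or without the replicate block, while 18 higher and 0 lower members passed with the block adjusted over the list alone and 0 without it. The call was lost when B10− replicate 2 was left out. In that fit the lower level of these genes in culture 2 than in culture 1 (median log2 difference -2.36) enters by construction.

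Replication-type histone genes, a group chosen after its values were seen, made up 69 tested entries, of which 66 were higher in both cultures and 35 were called higher with the replicate block. Their median log2 difference was 2.16 in culture 1 and 2.71 in culture 2. Hist1h1c was at 970 and 92.4 FPKM in B10+ against 214 and 19.8 FPKM in B10− cells, and Hist2h2aa2 at 580 and 118 against 48.2 and 21.2 FPKM (limma adjusted p with the block = 0.026 and 0.0464). Many of these genes are near-identical copies whose reads can be shared, so the value of a single histone gene is uncertain. The summed FPKM of all 69 entries was 61090 against 13460 in culture 1 and 7214 against 1436 in culture 2.

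Plasmablast and secretory genes were higher by a small margin, with a median log2 difference of 0.30 over 27 tested members, 18 higher and 3 lower in both cultures (camera adjusted p = 0.00206, and adjusted p = 0.865 with an estimated correlation). Sec11c, a signal peptidase subunit, rose over all genes with the replicate block, at 205 and 30.6 against 42.9 and 3.61 FPKM (limma adjusted p with the block = 0.0287). Prdm1 (Blimp-1, which drives plasma cell differentiation) was at 9.94 and 22.5 against 2.27 and 7.96 FPKM (limma adjusted p with the block = 0.0583). Ell2 and Fkbp11 had log2 differences of 0.76 ± 0.57 and 1.49 ± 1.32 (SD over 2 cultures). Prdm1, Sec11c, Igj and Edem1 passed with the block adjusted over the list alone, and 0 members without it. Without the block the list was not called with no filter on low values (camera adjusted p = 0.168), without B10− replicate 2 or without B10+ replicate 1, the last with the direction turned. With the block it was called (camera adjusted p = 0.000733, and 0.000487 with no filter on low values), but not with an estimated correlation (0.780).

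Unlike the B-1 and marginal zone list, the pan B cell, germinal centre and follicular lists and the transcription factors linked to Il10 were not called as groups. With 2 cultures this does not show that they were equal. Pan B cell genes (19 tested, 7 higher and 5 lower in both cultures) had a camera adjusted p of 0.685, germinal centre genes (8 tested, 3 and 1) 0.841, follicular B cell genes (17 tested, 5 and 6) 0.447, and transcription factors linked to Il10 (17 tested, 8 and 5) 0.898. Single members moved with the replicate block over all genes. Rgs13, a regulator of chemokine signalling in germinal centre B cells, rose from 9.72 ± 0.492 to 32.6 ± 2.58 FPKM (SD, n = 2; limma adjusted p with the block = 0.0449). S1pr1, the receptor for egress from lymphoid tissue, rose to 23.6 and 9.41 FPKM from 5.53 and 2.16 FPKM (limma adjusted p with the block = 0.0428), while Satb1 of the follicular list fell. Adjusted over the list alone with the block, Rgs13 was higher and Irf8 lower among germinal centre genes, Faim3 was higher among pan B cell genes, and S1pr1 and Cxcr4 were higher and Satb1, Gpr183 and Fcer2a lower among follicular genes. Among the transcription factors, Prdm1 and Bhlhe41 were higher and Irf8, Stat3, Bhlhe40 and Cebpb lower with the block adjusted over the list alone, and 0 passed over all genes. Irf8 was at 208 and 175 against 333 and 312 FPKM, and Bhlhe41 at 1.85 and 7.13 against 0.601 and 0.942 FPKM. In these 4 lists 0 members passed without the block under either adjustment. Rora, Cd180, Blnk, Cd79a, Fas and Bcl6 had log2 differences of 0.71, 1.05, -0.73, 1.07, 0.19 and -0.42.

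Genes of acute activation leaned to lower values in B10+ cells. Immediate early and calcium response genes (30 tested, 5 higher and 14 lower in both cultures, median log2 difference -0.06) had a camera adjusted p of 0.0611, and fell with the replicate block (0.044, and adjusted p = 0.78 with the block and an estimated correlation). Without the block it was 0.0377 with no filter on low values, 0.0397 with at least 5 FPKM in 2 libraries, 0.169 after quantile normalization and between 0.00085 and 0.886 with a library left out, and the blocked call was lost after quantile normalization (0.0729). NF-kB target genes (26 tested, 3 higher and 11 lower, median -0.13) had 0.251, and fell with the block (0.0484, and adjusted p = 0.873 with an estimated correlation), a call lost after quantile normalization (0.175) and with at least 5 FPKM in 2 libraries (0.081). Adjusted over the list alone with the block, Gem, Fosb, Cd69 and Myc were lower and Rgs16 and Rcan1 higher in the first list, and Cd83 and Icam1 were lower and Ebi3 higher in the second. Cd69 was at 229 and 909 against 583 and 2042 FPKM, and Myc at 28.6 and 249 against 56.6 and 449 FPKM. No member of either list passed over all genes with or without the block, and 0 passed without the block over the list alone. Nr4a1, induced by antigen receptor signals, was at 21.4 and 31.0 against 67.5 and 48.4 FPKM, and Nfkbia at 445 and 601 against 600 and 665 FPKM.

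Interferon-stimulated genes (28 tested, 15 higher and 6 lower in both cultures, median log2 difference 0.24) had a camera adjusted p of 0.082, and rose with the replicate block (0.021, and adjusted p = 0.78 with the block and an estimated correlation). Cmpk2 and Mx1 passed with the block adjusted over the list alone, and 0 members without it. Ifit3 was at 11.5 and 77.2 against 8.21 and 15.1 FPKM, and Oas2 had a log2 difference of -0.84 ± 0.54 (SD over 2 cultures). Without the block the list was called after quantile normalization (camera adjusted p = 0.0191) and with at least 5 FPKM in 2 libraries (0.0169), but not with no filter on low values (0.819), and its direction turned when B10− replicate 1 or B10+ replicate 2 was left out. Antigen presentation and costimulation genes (20 tested, 13 higher and 6 lower in both cultures) had a camera adjusted p of 0.249 at the 1 FPKM minimum and 0.0238 with at least 5 FPKM in 2 libraries, 0.195 after quantile normalization and 0.966 with no filter on low values. With an estimated correlation it was 0.919. With the replicate block it was 0.194, and 0.0593 with at least 5 FPKM in 2 libraries, so the call was lost there. Among these genes, Cd80 was at 36.9 and 32.6 against 13.5 and 1.34 FPKM, Icosl at 0.585 and 0.180 against 1.69 and 1.09 FPKM, and H2-Oa and Ciita had log2 differences of 0.71 and -0.64. Toll-like receptor and LPS sensing genes (20 tested, 7 higher and 5 lower) had a camera adjusted p of 0.685, a median of -0.05 and a mean of 0.11. Unc93b1, Tlr1 and Ly96 had log2 differences of -0.61, 0.88 and 0.56, and 0 members of these last 2 lists passed in either fit under either adjustment.

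**Figure D3:**
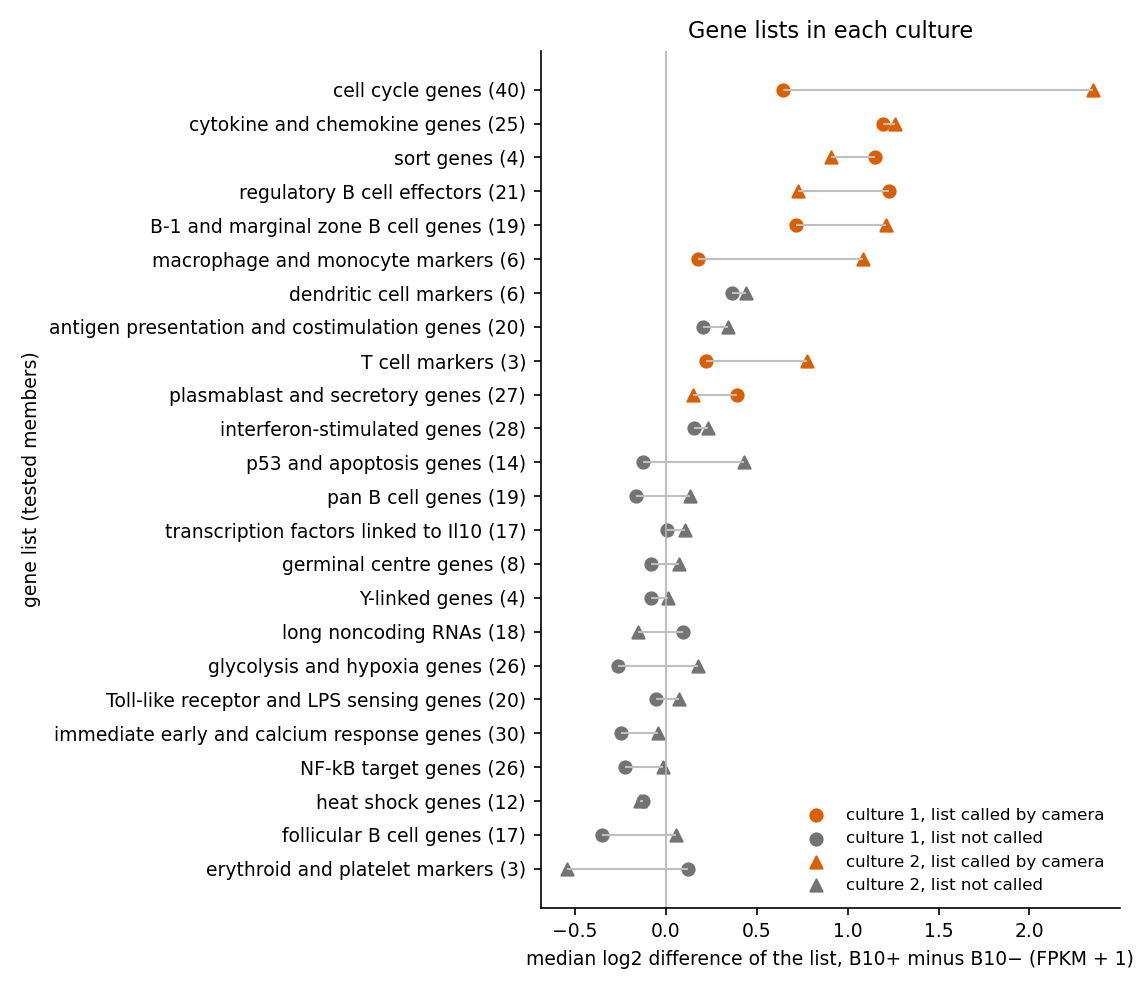
Median log2 difference between B10+ and B10− cells, log2(FPKM + 1), of the 24 tested gene lists (rows, with the number of tested members) in culture 1 (circles) and culture 2 (triangles), orange where camera called the list without the culture block. The cell cycle median is 0.65 in culture 1 and 2.35 in culture 2.

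Other programmes were not called as lists between the subsets, which does not show that they were equal. Glycolysis and hypoxia genes (26 tested) had a camera adjusted p of 0.685, p53 and apoptosis genes (14 tested) 0.560, heat shock genes (12 tested) 0.715, long noncoding RNAs (18 tested) 0.898 and Y-linked genes (4 tested) 0.898. For the long noncoding RNAs the median was -0.01 and the mean 0.07. Terc, the RNA template of telomerase, rose over all genes with the replicate block, at 161 and 141 against 65.3 and 47.6 FPKM (limma adjusted p with the block = 0.0459). Adjusted over the list alone with the block, Terc and Bag3 were higher and Vegfa and Bcl2l11 lower in their lists. Vegfa had a log2 difference of -1.18, and Bcl2l11 (the pro-apoptotic Bim) was at 10.3 and 62.0 against 20.6 and 149 FPKM. Hk1, Pfkl and Ndrg1 had log2 differences of 0.32, -0.59 and 0.64, Zmat3 and Casp8 of 0.54 and 0.37, Hspa1a, Hspa1b and Hspb1 of -0.78, -0.81 and 0.53, and Snhg4, Rpph1 and Snhg12 of -0.45, 0.95 and -0.32. The Y-linked genes Uty, Ddx3y, Kdm5d and Eif2s3y differed between the subsets by 0.14, -0.15, -0.06 and 0.05.

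Markers of other spleen cells were mostly below the 1 FPKM filter. Of 17 T cell markers, 3 were tested (Cd2, Lat and Lck) and were higher as a list (camera adjusted p = 0.0258, 0.0484 with the replicate block, and adjusted p = 0.712 with an estimated correlation). With no filter on low values, which brings in all 17 markers, the list was higher with a camera adjusted p of 5.03e-07, and 1.04e-05 with the replicate block. The call on the 3 genes was lost when any library was left out, with camera adjusted p between 0.0699 and 0.648, and with the block after quantile normalization (0.0775). Cd2 was at 20.3 and 10.3 against 5.24 and 2.93 FPKM, and passed with the block over the list alone, while Lat and Lck had log2 differences of 0.36 and 0.23. Among the markers below the filter, Cd3e, Cd3d, Cd3g and Cd4 reached at most 0.298, 0.253, 1.14 and 0.168 FPKM in any library. Cd8b1 was at 0.863 and 3.23 FPKM in B10+ cells and listed at 0 in both B10− libraries, and Zap70 was at 0.912 and 1.67 FPKM against 0 and 0.014 FPKM. Of the 11 NK cell markers only Il2rb, a chain of the interleukin 2 and 15 receptors, was tested. Il2rb rose from 2.40 ± 1.91 to 15.0 ± 9.95 FPKM (SD, n = 2; limma adjusted p with the block = 0.0307), and Ncr1 was listed at 0 throughout.

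Of 17 macrophage and monocyte markers in the table, 6 were tested and were higher as a list (camera adjusted p = 0.00206, and adjusted p = 0.712 with an estimated correlation), a call lost without B10− replicate 2 (0.171) or B10+ replicate 2 (0.131). With the replicate block it was 0.0276, and lost with no filter on low values (0.103) and with at least 5 FPKM in 2 libraries (0.0825). Apoe, an apolipoprotein, rose over all genes with the replicate block, from 9.76 ± 1.38 to 49.3 ± 2.22 FPKM (SD, n = 2; limma adjusted p with the block = 0.0287). Adjusted over the list alone, Apoe, Emr1 and Mpeg1 passed with the block, and Apoe also without it. Hmox1 was at 25.1 and 3.55 against 26.7 and 0.420 FPKM. Lyz2 and Csf1r reached at most 0.598 and 0.374 FPKM. Dendritic cell markers (6 tested) had a camera adjusted p of 0.251, with Cst3 and Fscn1 passing with the block over the list alone, and Ccr9 and Xcr1 at log2 differences of 0.46 and 0.41. Erythroid and platelet markers (3 tested) had 0.600. Hbb-b1 was at 28.9 and 43.7 against 39.4 and 80.8 FPKM and was lower over the list alone with the block, and Hbb-b2 and Gp9 had log2 differences of 0.34 and -0.21. Of the neutrophil, mast cell and basophil markers 0 were tested. S100a8 and S100a9 were listed at 0 in every library, and Kit reached at most 0.296 FPKM.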

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

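The fit with the culture as a replicate block moved the calls from 0 to 81 higher and from 0 to 8 lower entries, with 11 lists called (9 higher, 2 lower) in place of 8. It changed no list call other than the interferon, immediate early and NF-kB lists. Combinations with the block and the setting without loci under 200 bp were chosen after seeing the data. In the paired fit the higher and lower calls were 167 and 23 with quantile normalization, 40 and 5 with no filter on low values, 62 and 9 with at least 5 FPKM in 2 libraries, 53 and 7 with a pseudocount of 0.1, 72 and 9 with robust eBayes, and 126 and 10 without loci under 200 bp. Of the 89 calls, 87 were shared under quantile normalization and 45 with no filter. Without the block, limma called 0 and 0 in each of these settings except a pseudocount of 0.1, which called 0 higher and 1 lower entry (smallest adjusted p 0.0451), with 99 higher and 15 lower at an unadjusted p under 0.05 under quantile normalization. Quantile normalization moved the median of all entries to -0.07. Leaving out each library in turn without the block gave 1 to 130 higher and 3 to 14 lower entries and 9 to 14 lists, with 130 and 14 entries and 14 lists without B10− replicate 1. Such a fit holds a lone library of a subset, assumed to vary like the other subset, and sets unequal numbers of libraries per culture against each other, so the difference between cultures enters it by construction. With the block it could not be fitted with any residual degree of freedom.

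With an estimated correlation camera called 0 lists, with and without the replicate block (smallest adjusted p 0.780 and 0.198). With fry 1 list was called (the sort genes, adjusted p = 0.0192), and 0 with the block (smallest 0.098). Apart from the sort genes, the list calls were therefore made only with the preset correlation. Between the cultures, camera with an estimated correlation gave an adjusted p of 0.733 even for Y-linked genes, with a median log2 difference of -5.09. That setting tests on few residual degrees of freedom, so its losses do not show whether the calls depend on the preset correlation. With the block and all 4 libraries, the camera direction turned from higher to lower for the transcription factor, germinal centre and pan B cell lists, which passed in neither fit. For lists that passed before or after the turn, directions turned only when a library was left out. Adjusted p values after the turn were 0.8415 for plasmablast genes without B10+ replicate 1 (lowest with a library left out 2.894e-05). Without B10− replicate 1 they were 0.004901 for interferon-stimulated, 4.551e-05 for glycolysis and 3.337e-05 for Y-linked genes. Without B10+ replicate 2 they were 0.000839, 0.0009112 and 0.007848 for the same 3 lists. Without B10− replicate 2 they were 0.01499 for p53 genes and 0.02068 for long noncoding RNAs. The lowest values with a library left out were 1.074e-17 for interferon-stimulated, 1.136e-16 for glycolysis and 2.068e-14 for Y-linked genes, and the highest were 0.4162 for p53 genes and 0.749 for long noncoding RNAs. Y-linked genes differ between the cultures, so these calls show the culture difference entering the fit. Of 107 named genes, 87 kept a single direction in every setting run. Depth is unknown, so whether genes near 1 FPKM are limited by counting was not assessed.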

Other observations

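All tests in this part were chosen after the results were seen, as were the values on the Il10 neighbours and on the cultures. Only the bounds of the GC and length tests, and a first bound of the scaling test, were written before those tests were run. Genes lying next to Il10 on chromosome 1 (mm9) differed unequally. From Fcamr (132697479) to Ikbke (133176140), Il19 was the neighbour with the largest log2 difference, 3.22 and 3.85 in cultures 1 and 2. Il24 was at 6.24 and 1.37 FPKM in B10+ against 0.951 and 0.503 FPKM in B10− cells, Faim3 at 69.3 and 68.5 against 39.7 and 36.8 FPKM, and Mapkapk2, the next gene on the other side of Il10, at 199 and 148 against 116 and 48.2 FPKM. Il20, which lies between Il24 and Il19, was listed at 0 in all 4 libraries.

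The cultures differed from each other more than the subsets did. In the limma fit with both terms, 2162 entries were higher and 4237 lower in culture 2 than in culture 1, which compares these 2 cultures only, since the 2 libraries of a culture are not independent cultures. The mouse Y-linked genes Ddx3y and Eif2s3y were at 67.4 and 84.5 FPKM and at 99.8 and 103 FPKM in the B10+ and B10− libraries of culture 1, and at most 0.105 FPKM in culture 2. Xist was at 263 and 257 FPKM in culture 2 and at most 0.018 FPKM in culture 1. This is the pattern of male cells in culture 1 and of female cells in culture 2, though the labels give no sex. By these genes the only 2 replicates differ in sex. Glycolysis and hypoxia genes were lower in culture 2 (median log2 difference -2.19, 24 of 26 called lower and 1 higher, camera adjusted p = 7.16e-06, and adjusted p = 0.733 with an estimated correlation). Bnip3 was at 48.1 and 59.2 FPKM in culture 1 against 0.794 and 1.76 FPKM in culture 2, and Tpi1 at 872 and 1107 against 34.3 and 15.3 FPKM. Cell cycle genes were also lower in culture 2 (median -2.36, 34 of 40 called lower and 1 higher, camera adjusted p = 6.95e-05, and adjusted p = 0.733 with an estimated correlation). Interferon-stimulated genes were higher there (23 of 28 called higher and 1 lower, camera adjusted p = 4.56e-10, and adjusted p = 0.733 with an estimated correlation). Each culture holds both subsets, so these differences do not enter the difference between subsets within a culture.

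For the higher cell cycle and histone genes of B10+ cells, removing the trend of the difference with GC content and transcript length, fitted on all other genes, left the cell cycle median at 0.64 in culture 1 and 2.27 in culture 2, from 0.65 and 2.35, and the histone median at 2.21 and 2.76, from 2.16 and 2.71, which argues against that bias as the whole cause. After quantile normalization the cell cycle medians were 0.63 (95% bootstrap interval over genes 0.273 to 0.863) and 2.09, above 0 in both cultures. A first bound of 50% of the starting median was missed by the lower end in culture 1 and left that test undecided, and it was replaced, after this was seen, by an interval above 0. Shared reads move signal between copies, yet the summed histone signal was higher by 2.18 and 2.33 on the log2 scale, a test that replaced a first version on 5 H1 genes (medians 2.18 and 2.41). For histones, a larger share of B10+ cells in S phase stays open, since 10 of 16 replication genes were higher in both cultures, with medians of 0.09 and 1.12, and 2 of 6 Mcm genes. The Mcm medians were -0.03 and 0.99. Of the mitotic genes of the cell cycle list, 22 of 22 were higher in both cultures, with medians of 0.94 and 2.875. In culture 1 the rise thus lay in the mitotic genes more than in the replication genes.

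B10+ cells carried genes known from T and NK cells and macrophages. Macrophages would bring their abundant transcripts, but the highest of C1qa, C1qb, C1qc, Lyz2 and Csf1r reached 0.555% of the level of Apoe in a B10+ library. All 5 of these genes lay below the filter, and they were chosen after values were seen. The outcome depends on leaving out Emr1, Mpeg1 and Hmox1. In the B10+ libraries Mpeg1 was at 9.87 and 149 FPKM and Hmox1 at 25.1 and 3.55 FPKM, beside 47.8 and 50.9 FPKM of Apoe. The comparison therefore does not decide whether macrophages were a source of Apoe. The highest gene of the T cell receptor complex and its coreceptors (Cd3g in culture 1, Cd8b1 in culture 2) reached 2.34% of the level of Ctla4, which argues against T cells as its main source. It reached up to 40.6% of that of Pdcd1, Xcl1 or Il2rb and up to 80.3% of that of Ifng or Il21. Both maxima come from Cd8b1 alone (3.23 FPKM) in the B10+ library of culture 2. There Cd3d, Cd3e and Cd3g were at 0.253, 0.298 and 0.245 FPKM, and Cd8a was listed at 0. A contribution of T cells to Pdcd1, Xcl1, Il2rb, Ifng and Il21 stays open, although both subsets were sorted as B cells per the labels. Cd2 (20.3 FPKM beside 244 FPKM of Ctla4 in culture 1, above the bound of 5%), Lat, Lck, Emr1, Mpeg1 and Hmox1 were not counted. The B10− libraries held them, but also the counted Cd3d (0.130 and 0.193 FPKM), Csf1r (0.0409 and 0.374 FPKM) and, in culture 2, Lyz2 (0.598 FPKM). Presence in B10− cells therefore does not separate the counted from the uncounted genes. Emr1 was at 2.58 and 2.55 FPKM in B10+ against 0.836 and 0.220 FPKM in B10− cells. The marker sets were changed more than once after values were seen, and another choice, with Emr1 counted for macrophages, had left Apoe open; no biological explanation was tested.

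Mir3096 and Mir219-1 stood out as listed at 0 in B10+ cells, with 9565 and 4707 FPKM and 250 and 131 FPKM in B10− cells. Entries that are at 0 in a library and at 20 FPKM or more in another numbered 28, and 24 of them (85.7%) span under 200 bp, against 64 of 10367 tested entries (Fisher's exact test, two-sided, p = 4.21e-50). The 28 were drawn from all 23699 entries, of which 801 span under 200 bp, so the test compares unlike sets. It also does not address why both B10+ libraries are at 0 and both B10− libraries are not. These values may therefore come from the instability of FPKM for loci shorter than a sequenced fragment. Mir3096 lies within AI506816, which was at 24.3 and 97.0 FPKM in B10+ against 29.5 and 148 FPKM in B10− cells. No biological explanation was tested for these entries.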
